A study of Arabidopsis thaliana with 25 samples.

How the data were processed

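Seedlings of Arabidopsis thaliana, accession Columbia, were sampled at 10 days from plates with 1% sucrose kept under 16 h of light, at 22 °C by day and 20 °C by night. The genotypes in the RNA data are wild type, the h1.1 h1.2 double mutant of linker histone H1 (called h1 here) and cmt2, a mutant of a methyltransferase that acts on cytosines outside the CG context. The heat treatment was 1 h at 4 °C followed by 24 h at 37 °C in the dark, so every heat comparison also includes the cold hour and the darkness. RNA sequencing covered 17 libraries, with 2 libraries of untreated h1 and 3 of each other group, from 50 mg of plant material each and read as 50 bp single ends; the labels call them biological replicates. Bisulphite sequencing, read as 150 bp pairs, covered wild type and h1, each untreated and after heat. The labels list 2 bisulphite replicates per group, but each deposited table holds 1 pooled column pair per group, so no bisulphite comparison here has a replicate test. Plants grown with zebularine, which the growth protocol mentions, were not analysed here. Tables of genes were not used here, so the transcripts of the mutated genes could not serve as a check of the labels.

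Per the submitters' processing notes, STAR 2.5.3, HTSeq, DESeq2 1.20.0, Bismark 0.16.3 and the TAIR10 genome were used, with no role or order given. Each RNA table covers 1 pair of groups and lists transposable elements (TEs) with at least 2 reads over its libraries. Its signal values are reads per TE that the authors divided by a size factor per library. Each value was a whole multiple of the value of 1 read, so the deposited signal gave back whole reads for 100% of values within a tolerance of 0.001, and the reads of a library were identical in every table that holds it. The size factors equalled median-of-ratios factors recomputed from the TE values alone, so levels are relative to other TEs and not to gene transcripts. The log2 fold changes with their standard errors, the Wald score and the p-values, raw and adjusted, are the authors' DESeq2 output, per the file headers. Other deposited score columns, named for H1, are not described in the labels and were not used here. The methylation tables give per cytosine the count of methylated and of unmethylated reads, which the authors made per the file headers. How strand, reads with several positions and TEs inside genes were counted, and how bisulphite reads were trimmed, deduplicated or checked for conversion, is not given in the sources used here. Copies of one TE family share sequence, so reads of near-identical copies cannot be told apart. All 52 library columns of the RNA tables were used. They name 11376 TEs, of which 10661 have coordinates and 10654 carry the authors' pericentromere flag. The 715 without coordinates have no TE methylation level here. Letters A to C were given here to libraries of h1 and of heated cmt2, whose column numbers do not match the replicate numbers of the labels in full.

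The comparisons, tests, thresholds, TE lists, naming rule and most alternatives were fixed before the data were examined. Each comparison was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2 of the normalized value plus a pseudocount of 1, using the libraries of the 2 groups compared. A fold change on this scale understates the change of weakly expressed TEs. A TE was called at a Benjamini-Hochberg adjusted p below 0.05 with an absolute log2 fold change of at least 1. The plan named the deposited DESeq2 calls first, edgeR where a table held raw reads, and limma where it held normalized values and no reads. The tables hold normalized values, so limma on all TEs of a table was taken as the planned fit, although whole reads could be recovered. On reads simulated from the real means and library sizes, with 200 TEs changed, that fit failed in each of 9 comparisons under a rule of at most 10% false calls and at least 80% of 8-fold changes recovered. For heat in h1, 57.1% of its calls over 8034 TEs were false, and for heat in cmt2 it recovered 13.8% of 8-fold changes over 6436 TEs. The fit was therefore restricted to TEs with a deposited adjusted p, which met the rule in 9 of 9 comparisons. A fit of TEs with a mean of at least 10 met it in 9 as well, and a robust fit of all TEs in 1. This decision rested on simulated data but was taken after real counts of 6 versions had been seen: limma on all TEs, with that mean filter, with pseudocounts of 0.5 and 4, the deposited DESeq2 calls and edgeR. With it, 8-fold changes were recovered at between 95.9% (heat in cmt2, 2318 TEs) and 100.0% (heat in wild type, 2934 TEs). The 4-fold changes were recovered at between 67.6% (heat in cmt2) and 95.5% (heated h1 against untreated wild type, 3070 TEs), and 2-fold changes at between 9.70% and 33.1% for the same comparisons. These shares hold for TEs with a mean of at least 10. Of the TEs called with heat, 600 in wild type, 537 in h1 and 464 in cmt2 had a lower mean.

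Counts on the recovered reads with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) and the deposited DESeq2 calls, both named in the plan, serve as alternatives here. That role was given to them after the data were seen. The difference between 2 genotypes in heat response is the difference of their deposited log2 fold changes, tested as a Wald z with adjustment over TEs that have an adjusted p in both tables. On simulated values for cmt2 over 2221 TEs it recovered 44.8% of differences of 2, 86.6% of 3 and 93.9% of 4 on the log2 scale. The differences were placed only at TEs with a standard error below 1, so these shares do not hold for TEs with a larger one. Such TEs include AT1TE31080, AT1TE36160 and AT1TE75790, with standard errors of 1.30, 1.22 and 1.15. Interactions in edgeR and limma are its alternatives. Superfamilies and pericentromeric location among called TEs were compared with all tested TEs by two-sided Fisher's exact tests. Those tests treat related copies as independent, so their p-values are too small.

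The text names, per comparison, TEs among the 10 largest increases and the 10 largest decreases called with a mean of at least 10, and members of fixed lists. The lists are 8 full-length copies of ONSEN, all ATCOPIA78 members, other LTR elements studied under heat or as mobile elements, ATHILA, CACTA, MULE, Helitron, LINE, and SINE with SADHU. CACTA stands for 4 ATENSPM families (1A, 3, 5 and 6), MULE for VANDAL3, VANDAL6, VANDAL21, ATMU1, ARNOLDY1 and ARNOLDY2, and Helitron for the ATREP and HELITRONY families, so other families of these superfamilies are in no list. For each list, calls are given over all tested TEs and adjusted over the list alone. The planned lists of protein-coding genes had no values to test.

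Methylation levels weight cytosines by reads, at cytosines with a coverage of at least 4 on chromosomes 1 to 5, with 95% Wilson intervals. Intervals and floors cover counting error only, since amplified reads are not independent molecules. TE levels needed at least 10 cytosines and 100 reads in each group and were averaged by length (4000 bp or more, 500 to 4000 bp, under 500 bp) and by the pericentromere flag, which replaced the planned gene density of windows. Levels of the single ONSEN copies and their medians are given without this minimum. Bins of 100 bp with at least 4 cytosines were compared by Fisher's exact test. A bin was called at an adjusted p below 0.01 and a difference of at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points. On simulated bins for h1 against untreated wild type, the test recovered 98.0% of CG changes of 50 points over 682039 bins, 73.5% of CHG changes of 30 points over 738513 bins and 92.5% of CHH changes of 15 points over 1174746 bins. Such a test compares 2 pooled libraries and not the conditions. Methylation of genes and a background from chloroplast cytosines were not analysed here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

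Replicates of every group differed beyond sampling noise; the closest pair, heated cmt2 A and B, had a chi-square per degree of freedom of 7.98, and each was counted separately. Reads on TEs ranged from 158358 to 1137311 per library. Replicate numbers are shared by untreated and heated wild type and by untreated cmt2 and untreated wild type. Deviations from the group means correlated across TEs at 0.44, 0.64 and 0.24 for the same numbers of cmt2 and wild type, each over 0.1, so these numbers were taken to pair the libraries, although cmt2 replicate 3 correlated slightly better with wild type replicate 1 (0.247). A fit with the replicate number as a block called 5 TEs there against 4 without it. The values given below for untreated cmt2 nevertheless come from the fit without the block. With it, 0 of 8 ONSEN copies were called in untreated cmt2 (limma adjusted p from 0.61 to 0.89). Alternatives changed the thresholds, the set of TEs, the pseudocount, the centring, the tool, the coverage minimum, the weighting, the bin size and the libraries included.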

Results

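The RNA data follow TE transcripts in wild type, h1 and cmt2 seedlings before and after a day of heat, and the bisulphite data follow DNA methylation in wild type and h1. In each RNA library few TEs hold many of the reads. The single largest TE took between 7.20% and 35.3% of TE reads. It was AT2TE28180 or AT3TE32730 in untreated libraries, and AT4TE34010 or the ONSEN copy AT1TE12295 after heat. Reads on TEs ranged from 158358 (untreated cmt2, replicate 2) to 1137311 per library. Without gene models it is not known whether reads on the most abundant fragments come from transcripts of genes that overlap them. Untreated cmt2 replicate 2 correlated at 0.642 with replicate 1 across TEs, and heated cmt2 C at 0.895 and 0.907 with A and B, which correlated at 0.964 with each other.

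Heat changed TE transcripts in wild type in both directions. Of the 10 largest increases 8 were at pericentromeric LTR elements, and the other 2 were AT1TE45380 of ATENSPM7 (log2 8.37) and AT3TE62570 of ATHAT7 (8.36). The Copia element ROMANIAT5, a family known as responsive to heat, has copies on chromosomes 1 and 3. Its copy AT1TE43225 (chromosome 1, 13230993 to 13235723) rose from 11.8 ± 6.87 to 4777 ± 713 normalized reads (mean ± SD, n = 3 each; log2 fold change 8.68, SE 0.39, adjusted p = 2.1e-07). AT3TE51895 (chromosome 3, 12603266 to 12606828) rose from 3.58 ± 2.2 to 2004 ± 457 (log2 fold change 8.90, SE 0.41, adjusted p = 2.4e-07), AT1TE51360 by 8.31 and the adjacent ATCOPIA28 copy AT3TE51900 by 8.83 on the log2 scale. Among Gypsy elements, AT4TE15820 of ATLANTYS2 rose by 8.39 and AT2TE28025 of ATGP10 by 8.44. AT3TE59350 of ATHILA4A, a Gypsy lineage that fills the regions around centromeres, had 0 reads in untreated wild type and rose at least 354-fold.

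Other elements lost transcripts in heated wild type. The Copia copy AT4TE42860 of ATCOPIA4 fell from 2490 ± 916 to 20.7 ± 1.40 (log2 -6.78, SE 0.29, adjusted p = 2.1e-07), AT5TE49725 of ATCOPIA12 changed by -5.94 and AT4TE10320 of ATCOPIA93 by -5.54. The Helitron copy AT3TE63500 of ATREP1 fell from 258 ± 102 to 0.925 ± 0.887, and the LINE copy AT2TE04800 of ATLINE1_3A changed by -5.18 on the log2 scale; each of these 2 had 4 reads left over the heated libraries. AT2TE32080 of the CACTA family ATENSPM1A changed by -5.43. EVADE (AT5TE20395), a Copia element known to move in plants without CG methylation, was not called (log2 0.28, adjusted p = 0.64).

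Of 2934 TEs tested in wild type, limma called 755 higher and 488 lower after heat. edgeR called 396 and 289, the authors' deposited table called 542 and 321, and 613 TEs were called by all of them without a difference in sign. The median of all tested TEs was shifted to 0.17 by heat in wild type, 0.24 in h1 and 0.04 in cmt2, and centring on it gave 696 and 568 calls in wild type. Pericentromeric TEs made up 66.1% of the TEs called higher against 45.1% of those tested (Fisher's exact test, adjusted p = 1.5e-40), and 29.3% of those called lower. LTR/Gypsy elements were called higher in 371 of 668 cases (odds ratio 6.12, adjusted p = 1.2e-79). Helitrons went the other way, with odds ratios of 0.250 for higher and 2.13 for lower calls. HAT elements were more often lower (odds ratio 2.42), and MuDR (0.585), Harbinger (0.120) and LINE/L1 (0.555) elements were less often higher.

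The fixed lists hold some families of their superfamilies only. In them, heat in wild type raised 8 of 8 ONSEN copies and 13 of 13 ATCOPIA78 members, with equal counts adjusted over the list alone. ATHILA had 174 higher and 10 lower of 281 (adjusted over the list alone 190 and 11), other LTR elements 60 and 12 of 146 (63 and 12) and MULE 48 and 6 of 113 (48 and 6). Helitrons had 52 and 137 of 524 (adjusted over the list alone 48 and 134). CACTA elements had 21 and 26 of 124 (21 and 26), with a median log2 fold change of 0.02 and a mean of -0.07, so neither value shows a direction. LINE elements had 22 and 7 of 109 (19 and 7), and SINE with SADHU elements 3 and 5 of 18 (3 and 5).

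In h1 the same kinds of elements rose with heat. AT4TE15820 of ATLANTYS2 rose from 2.07 ± 0.125 (n = 2) to 4536 ± 993 (n = 3; log2 10.51, SE 0.24, limma adjusted p = 1.6e-08), and AT1TE43225 of ROMANIAT5 from 5.05 ± 4.09 to 6036 ± 1131 (log2 10.13). The ATGP10 fragments AT1TE47520 and AT1TE47300, with 0 reads in untreated h1, rose at least 1215-fold and 1121-fold, and AT3TE59350 of ATHILA4A at least 674-fold. The LINE copy AT5TE55640 of ATLINE1_3A fell from 217 ± 37.3 to 2.74 ± 0.404 (log2 -5.86, SE 0.31, limma adjusted p = 9.7e-07). AT4TE54820, a fragment of the Mutator-like family ATMU9, fell from 11930 ± 371 to 362 ± 153 (log2 -5.12), while AT5TE49725 changed by -6.06, AT2TE32080 by -5.54 and AT4TE10320 by -5.12. EVADE was not called (log2 -0.32, adjusted p = 0.72).

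Limma called 829 TEs higher and 517 lower with heat in h1 of 2583 tested, edgeR 545 and 392, and the authors' deposited table called 619 and 334; all of them called 794, and centring gave 760 and 619. Without untreated h1 A limma called 701 higher and 315 lower, and without untreated h1 B 659 and 301. Gypsy elements were called higher in 425 of 657 cases (Fisher's exact test, odds ratio 6.89, adjusted p = 9.4e-89), Helitrons less often (0.303) and more often lower (2.2), and HAT elements more often lower (2.95). Pericentromeric TEs were 68.4% of the higher calls against 47.0% of those tested (adjusted p = 5.8e-50) and 36.9% of the lower calls. ONSEN rose in 8 of 8 and ATCOPIA78 in 13 of 13, also adjusted over the list alone. ATHILA had 215 higher and 13 lower of 295 (list alone 223 and 14), other LTR elements 49 and 18 of 128 (49 and 18), MULE 49 and 10 of 101 (51 and 10), Helitrons 54 and 125 of 381 (52 and 119), and SINE with SADHU 4 and 7 of 18 (4 and 7). CACTA had 25 higher and 20 lower of 113 (list alone 25 and 19) with a median of -0.38, and LINE 20 and 19 of 102 (20 and 16) with a median of -0.12 and a mean of 0.18, so median and calls differ in direction.

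In cmt2, ATCOPIA78 sequences were among the largest increases with heat. The fragment AT1TE10935 rose from 3.47 ± 0.829 to 6504 ± 1644 (n = 3 each; log2 10.49, SE 0.30, limma adjusted p = 7.6e-07). AT1TE43225 of ROMANIAT5 rose from 4.98 ± 3.58 to 5593 ± 2456 (log2 10.06, SE 0.59, limma adjusted p = 7.6e-06), and AT2TE28030 of ATGP10, with 0 reads untreated, at least 1169-fold. AT4TE42860 fell from 1578 ± 210 to 21.2 ± 6.06 (log2 -6.18), AT4TE54820 of ATMU9 from 7586 ± 5365 to 70.4 ± 76.6 (log2 -7.03), and AT5TE49725 changed by -5.80. AT4TE42895 of ATCOPIA93, without reads after heat, fell by at least 46.6-fold. EVADE was not called (log2 0.33, adjusted p = 0.71).

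Of 2318 TEs tested in cmt2, limma called 605 higher and 435 lower after heat, edgeR 346 and 284, and the authors' deposited table called 481 and 334, with 554 called by all of them. Gypsy elements were called higher in 278 of 536 cases (Fisher's exact test, odds ratio 4.79, adjusted p = 4.2e-48), Helitrons less often higher (0.355) and more often lower (1.84), and 63.0% of the higher calls were pericentromeric against 43.1% of those tested (adjusted p = 7.7e-30). ONSEN rose in 8 of 8 copies (8 adjusted over the list alone) and ATCOPIA78 in 15 of 16 (15). ATHILA had 136 higher and 12 lower of 222 (list alone 137 and 12), other LTR elements 37 and 11 of 119 (37 and 11), MULE 42 and 9 of 92 (45 and 9), CACTA 16 and 27 of 104 (15 and 26), Helitrons 52 and 108 of 389 (52 and 106), LINE 14 and 11 of 78 (14 and 9), and SINE with SADHU 1 and 8 of 17 (1 and 8). The heat comparisons of the genotypes use separate libraries. Of TEs tested in both, 629 were called higher in wild type and in h1 (223 by chance, odds ratio 105), 497 in wild type and in cmt2 (176 by chance, odds ratio 49.1, adjusted p = 1.7e-246) and 527 in h1 and in cmt2 (189 by chance, odds ratio 78.4). Lower calls were shared by 319 (86.3 by chance), 316 (79.6) and 314 (87.4) TEs. Those p-values treat related copies as independent.

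ONSEN, the Copia element best known for activation by heat, took up a far larger part of TE reads after heat in the mutants. The 8 full-length copies held 0.252 ± 0.114% of TE reads in untreated wild type, 0.101 ± 0.0298% in untreated h1 (n = 2) and 0.248 ± 0.172% in untreated cmt2. After heat they held 15.9 ± 4.89% in wild type, 42.4 ± 6.84% in h1 and 77.4 ± 8.28% in cmt2 (n = 3 each). The copy AT1TE12295 rose from 139 ± 27.9 to 14217 ± 2515 reads in wild type, from 61.9 ± 7.97 to 41538 ± 5527 in h1 and from 103 ± 26.2 to 97705 ± 22449 in cmt2. Over the copies the median log2 fold change was 6.72 in wild type (6.47 to 6.86; median SE 0.29, limma adjusted p from 2.1e-07 to 2.5e-07). It was 9.41 in h1 (9.15 to 9.58; SE 0.27, adjusted p from 1.7e-08 to 3.1e-08) and 9.97 in cmt2 (9.84 to 10.11; SE 0.41, adjusted p from 1.6e-06 to 1.8e-06). The near-identical copies share reads, so these are 8 readings of one family and not 8 independent observations.

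**Figure D1:**
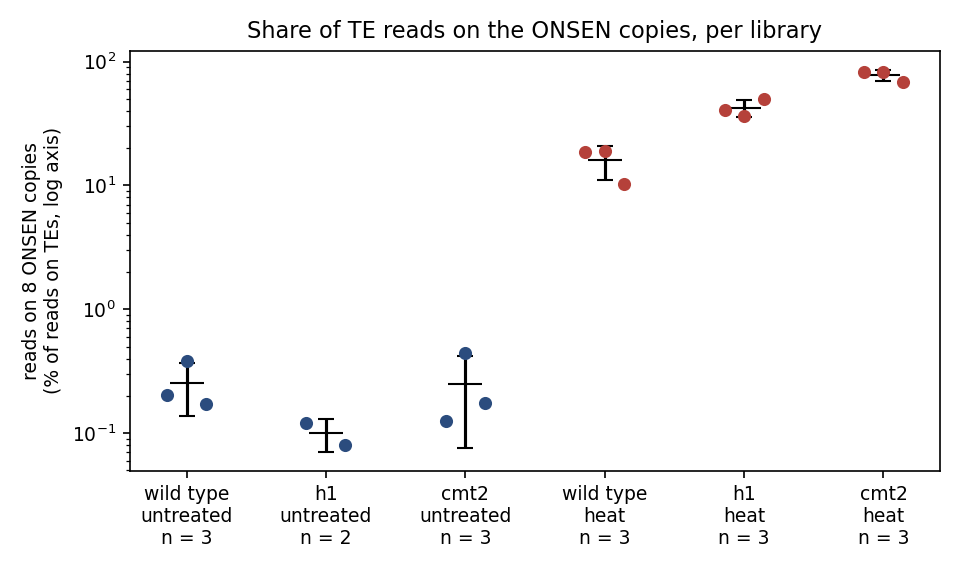
Share of TE reads on the 8 full-length ONSEN copies in each library, on a log axis. Points are libraries and bars the mean ± SD of a group.

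Between h1 and wild type without heat, few TEs differed. AT1TE93275, a HELITRON1 copy on the arm of chromosome 1 (28515062 to 28516118), was higher in h1 with 50.7 ± 5.02 (n = 2) against 2.2 ± 1.89 (n = 3; log2 4.16, SE 0.51, limma adjusted p = 0.0072). AT3TE51150 of the CACTA family ATENSPM11 (chromosome 3, 12348429 to 12350350) reached 188 ± 31.7 against 21.8 ± 1.76 (log2 3.04, SE 0.24, limma adjusted p = 0.00067), AT3TE68090 of ATCOPIA81 was higher by 3.63 and the SADHU copy AT3TE60310 by 3.27. Lower in h1 were AT4TE42860 of ATCOPIA4 (443 ± 74.3 against 2532 ± 878, log2 -2.47, limma adjusted p = 0.0072), the ATRE1 pair AT1TE72060 and AT1TE71950 (-2.11 and -2.08) and AT3TE63500 of ATREP1 (-2.15). The ONSEN copies were lower by a median of -1.48 (-1.67 to -1.27; adjusted p from 0.021 to 0.040).

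Limma called 17 TEs higher and 19 lower of 1591 in untreated h1, edgeR 21 and 12, and the authors' deposited table called 13 and 18, with 24 called by all of them. Untreated h1 has 2 libraries, and leaving out 1 of them leaves too few to judge the calls. Without h1 A or h1 B the median ONSEN difference was -1.60 and -1.32. The ONSEN calls dropped to 5 without wild type replicate 1 and to 3 without wild type replicate 2. Over these fits the log2 differences of the copies stayed between -1.75 and -1.13. LTR/Copia elements were more often lower (Fisher's exact test, odds ratio 10.5, adjusted p = 1.7e-05), which was lost without ATCOPIA78 (adjusted p = 0.353), and elements without a superfamily more often higher (9.95, adjusted p = 0.0090). In the lists, ONSEN had 8 of 8 lower (8 adjusted over the list alone), ATCOPIA78 8 of 10 lower (8), Helitrons 1 higher and 4 lower of 287 (1 and 4), ATHILA 1 lower of 43 (1), CACTA, a list without ATENSPM11, 1 lower of 91 (0), MULE 1 higher of 55 (1) and SINE with SADHU 1 higher of 16 (1). Of other LTR elements limma called 0 of 65 (0), and of LINE elements 0 of 60 (2 higher). EVADE was not called (log2 1.17, adjusted p = 0.40).

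After heat, 76 of the 92 TEs higher in h1 than in wild type were pericentromeric, and 55 were Gypsy elements. The Copia copy AT3TE76225 of ATCOPIA52 (chromosome 3, 18791152 to 18796089) showed the smallest p-value of the named increases, with 72.6 ± 5.42 against 6.63 ± 2.45 (n = 3 each; log2 3.32, SE 0.32, limma adjusted p = 0.00031). The ATHILA2 pair AT1TE47525 and AT1TE47305 was higher by 2.44 and 2.43 (881 ± 360 against 153 ± 16.1 for the first, limma adjusted p = 0.0015), AT5TE40105 of ATGP10 by 2.67 (94.4 ± 8.34 against 15 ± 6.54) and AT1TE93275 of HELITRON1 by 3.93. Lower in h1 were the LINE copy AT5TE08630 of ATLINE1_1 (21.8 ± 3.62 against 161 ± 95, log2 -2.60), AT2TE29180 of ATREP3 (-2.44) and AT2TE28350 of HELITRON3 (-2.36). The ONSEN copies were higher in h1 by a median of 1.1 (1.03 to 1.14; adjusted p from 0.030 to 0.053, 7 of 8 called).

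Limma called 92 TEs higher and 49 lower of 1819 in heated h1, edgeR 120 and 58, and the authors' deposited table called 86 and 78, with 117 called by all of them. The counts of higher and lower TEs were 40 and 29 without h1 A, 48 and 23 without h1 B, 68 and 19 without h1 C, 75 and 21 without wild type replicate 1, 101 and 114 without wild type replicate 2, and 67 and 17 without wild type replicate 3. The named TEs above ONSEN kept their call without any library. Of the ONSEN copies 0 were called without h1 A, h1 B, h1 C, wild type replicate 2 or wild type replicate 3, with log2 differences still between 0.95 and 1.22. With all libraries, edgeR and the authors' deposited table each called 8 of 8, and limma at an adjusted p of 0.01 called 0. Gypsy elements were called higher in 55 of 529 cases (Fisher's exact test, odds ratio 3.93, adjusted p = 4.1e-09) and MuDR elements less often (0.173). Pericentromeric TEs were 82.6% of higher calls against 46.8% of those tested (adjusted p = 1.9e-12) and 65.3% of lower calls (adjusted p = 0.0158). ATHILA had 26 higher of 238 (adjusted over the list alone 27 higher, 1 lower), other LTR elements 3 higher and 8 lower of 100 (3 and 9), Helitrons 2 and 7 of 202 (2 and 7), LINE 1 and 6 of 66 (1 and 6), CACTA 1 and 1 of 88 (1 and 0), MULE 1 and 2 of 77 (0 and 2) and SINE with SADHU 1 higher of 15 (2 and 2). ONSEN had 7 of 8 (8) and ATCOPIA78 10 of 12 (11) higher. EVADE was not called (log2 0.51, adjusted p = 0.73).

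In untreated cmt2 only 4 TEs passed the test against wild type. AT1TE93275 of HELITRON1 was higher (26.2 ± 4.43 against 1.91 ± 1.64, n = 3 each; log2 3.35, SE 0.46), as were AT3TE51150 of ATENSPM11 (74.3 ± 15.9 against 18.8 ± 1.52; log2 1.91, SE 0.24) and AT5TE34980, which has no assigned family (log2 3.13). AT5TE46165 of VANDAL20, a Mutator-like family, was lower (22.1 ± 3.24 against 70.4 ± 3.09; log2 -1.63, SE 0.21). Each had a limma adjusted p of 0.048. ONSEN was not called, with a median of -0.32 and adjusted p from 0.97 to 1.00. Limma called 3 higher and 1 lower of 1329, edgeR 5 and 1 and the authors' deposited table called 7 and 4; 83 TEs had an unadjusted p below 0.05. The count was 0 without cmt2 replicate 1, cmt2 replicate 2, cmt2 replicate 3, wild type replicate 1, wild type replicate 2 or wild type replicate 3. The fixed lists leave out HELITRON1, ATENSPM11 and VANDAL20, and no member was called in any of them, with 8 ONSEN copies, 9 ATCOPIA78 members, 54 other LTR, 38 ATHILA, 84 CACTA, 44 MULE, 218 Helitron, 49 LINE and 15 SINE with SADHU elements tested. Adjusted over the list alone, ATHILA had 1 higher and 1 lower and SINE with SADHU 1 higher, and each other list 0.

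Of the TEs called higher in heated cmt2, those with the most reads belong to ATCOPIA78. The pericentromeric copy AT3TE59075 reached 4090 ± 394 against 543 ± 93.9 in heated wild type (n = 3 each; log2 2.92, SE 0.24, limma adjusted p = 0.00057). The 8 ONSEN copies were higher by a median of 2.83 (2.75 to 2.87; SE 0.36, adjusted p from 0.0033 to 0.0036). AT2TE77015 of the Gypsy family ATGP9B was higher by 3.51 (39.2 ± 2.98 against 2.98 ± 2.51, limma adjusted p = 0.0033) and the related fragment AT4TE38410 by 3.95. Lower in cmt2 were AT3TE32730 of ATGP1 (6760 ± 2474 against 53306 ± 18622; log2 -2.98, limma adjusted p = 0.0039), AT2TE28350 of HELITRON3 (-4.05) and AT2TE28260 of ATCOPIA38 (-3.80). EVADE was not called (log2 0.01, adjusted p = 0.99).

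Limma called 24 TEs higher and 26 lower of 2016 in heated cmt2, edgeR 22 and 4, and the authors' deposited table called 26 and 65, with 26 called by all of them. The counts of higher and lower TEs were 2 and 0 without cmt2 A, 2 and 0 without cmt2 B, 33 and 183 without cmt2 C, 11 and 1 without wild type replicate 1, 25 and 69 without wild type replicate 2, and 19 and 2 without wild type replicate 3. AT3TE59075 kept its call in each case. The ONSEN copies were not called without cmt2 A or cmt2 B (0 of 8, log2 2.68 to 2.80, adjusted p from 0.068 to 0.073). With all libraries, edgeR and the authors' deposited table each called 8 of 8. LTR/Copia elements were more often higher (Fisher's exact test, odds ratio 5.78, adjusted p = 0.00062), and without ATCOPIA78 0 of 251 were. ONSEN had 8 of 8 higher (8 adjusted over the list alone), ATCOPIA78 11 of 14 (13), MULE 2 higher and 2 lower of 80 (2 and 5), Helitrons 2 and 2 of 258 (2 and 0) and ATHILA 1 and 2 of 238 (0 and 0). Other LTR elements had 3 lower of 110 (list alone 9 lower), CACTA 1 lower of 96 (0), LINE 0 of 72 (0) and SINE with SADHU 0 of 13 (1 lower). Both mutants are compared with the same heated wild type libraries, which alone links the differences. Their correlation across 1034 TEs was 0.649 against 0.506 in simulations without a change in either mutant, and the covariance 0.536 against 0.0951, a difference of 0.441. The mutants shared 12 higher TEs (0.911 by chance if independent) and 10 lower TEs (0.728) of 1751. The 12 include the 7 ONSEN copies called in heated h1, which share reads and are not independent.

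Heated mutants were also compared with untreated wild type. Limma called 1013 TEs higher and 526 lower of 3070 in heated h1 (edgeR 465 and 350, the authors' deposited table called 713 and 366), or 861 and 687 after centring on the median of 0.36, which moved the share of higher calls from 65.8% to 55.6%. In heated cmt2 it called 681 higher and 540 lower of 2453 (edgeR 369 and 337, the authors' deposited table called 527 and 367). These counts add the mutation and the heat and cannot separate them.

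**Figure D2:**
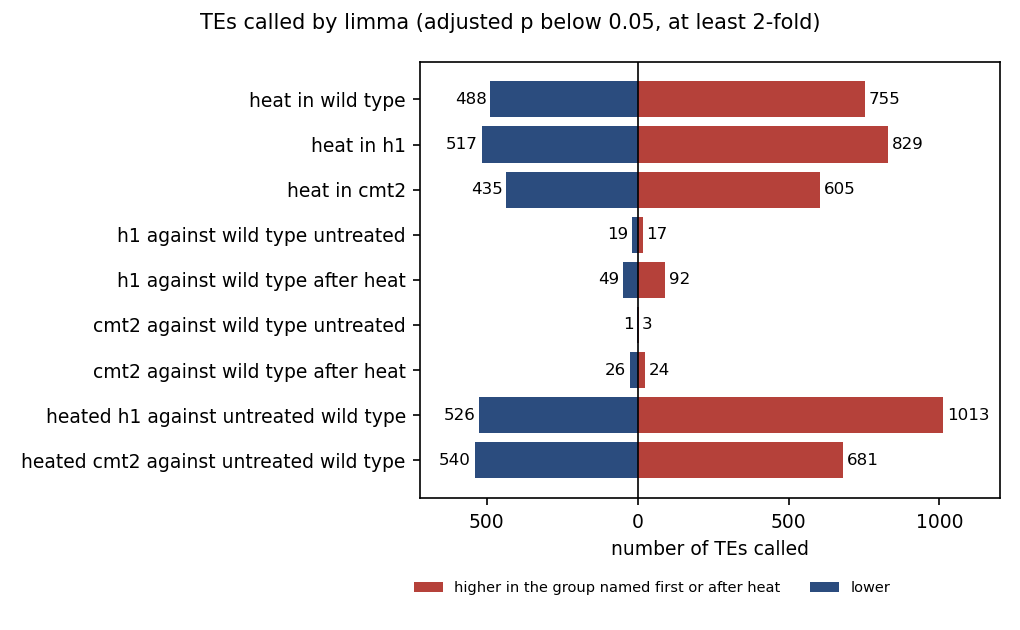
Number of TEs called higher (red) and lower (blue) by limma in each comparison, at an adjusted p below 0.05 and at least 2-fold.

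The heat response itself differed between genotypes at few TEs. In h1 against wild type the 8 ONSEN copies responded more strongly by a median of 2.71 on the log2 scale (2.44 to 2.96, adjusted p from 4.1e-07 to 8.7e-06), as the difference of fold changes in the authors' deposited tables. For these copies the evidence was weaker in the interaction tests, with adjusted p from 0.0087 to 0.014 in edgeR and from 0.0018 to 0.0022 in limma. AT4TE42860 of ATCOPIA4 fell less in h1 (-4.17 against -6.91 in the authors' deposited table, difference 2.74). Its untreated level was already lower in h1, so this difference does not by itself show a higher level after heat. AT5TE41395 of HELITRON5 rose more in h1 (9.03 against 6.77 in the deposited tables, difference 2.26). AT5TE58950 of HELITRONY1B fell less in h1 (2.53) and in cmt2 (2.41). In all, 11 TEs had a higher and 2 a lower response in h1 of 2357 tested; edgeR gave 11 and 0, sharing the ONSEN copies and AT4TE42860, limma 21 and 3, and centring 10 and 5 (84.6% to 66.7% higher). The lower ones were AT5TE46155 of VANDAL20 (-1.87) and AT5TE17365 of TAT1_ATH (-1.88).

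In cmt2 the ONSEN copies responded more strongly by a median of 3.27 (3.13 to 3.39, adjusted p from 8.1e-09 to 1.8e-07), and the ATCOPIA78 fragment AT1TE10935 by 3.97 (10.84 against 6.87 in the authors' deposited tables). For the ONSEN copies the interaction tests gave adjusted p of 0.011 in edgeR and from 0.0023 to 0.0032 in limma. A weaker response was called for 9 elements of TAT1_ATH (median -2.88, adjusted p from 0.033 to 0.041), 8 of them in 1 cluster on chromosome 1, and for 2 ATGP1 fragments, AT1TE31080 (-5.38) and AT1TE75790 (-4.19). In all, 10 TEs responded more and 13 less in cmt2 of 2221 tested, with 159 at an unadjusted p below 0.05. edgeR called 9 and 0, with 0 of the 13 among its calls, limma 9 and 1, and centring 10 and 2 (43.5% to 83.3% higher), so only the ATCOPIA78 part holds across methods.

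Genome-wide, methylation was higher in h1 than in wild type in CG and CHG contexts. Without heat, CG stood at 26.3% in wild type and 27.8% in h1, CHG at 7.62% and 9.82%, and CHH at 2.18% and 2.49%, from 1 pooled library pair per group (95% Wilson interval of the first 26.26% to 26.27%). After heat, CG stood at 25% and 25.6%, CHG at 7.06% and 8.75%, and CHH at 1.95% and 2.44%. The CHH difference of 0.311 points became -0.162 when 23293 cytosines covered by more than 500 reads in untreated wild type were left out, and that of 0.491 points after heat became 0.0201. As a mean of site levels, the difference after heat was 1.49 points in CG against 0.595 weighted by reads, and 2.75 against 1.69 in CHG.

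Methylation in h1 depended on the length and place of TEs. In 864 pericentromeric TEs of at least 4000 bp, the mean CHG level was 64.5% in h1 against 43.4% in wild type (difference 21 points, higher by 10 points or more in 94.2% of TEs). CG was higher there by 8.33 points and CHH by 1.70 points. In TEs of 500 to 4000 bp on chromosome arms it went the other way, with CHG at 16.6% against 21% over 2154 TEs (difference -4.34 points, or -1.71 weighted by reads) and CHH at 4.14% against 6.58% over 2475 TEs (-2.44 points), while CG differed by 0.382 points (1.43 weighted by reads). Pericentromeric TEs of that length had 10.7 points more CHG and 5.37 more CG. Class means differed little with heat. Long pericentromeric TEs differed after heat by -1.24 points in CG, -0.789 in CHG and -0.297 in CHH in wild type, and by -1.06, -1.57 and 0.295 in h1. No test across replicates was possible.

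**Figure D3:**
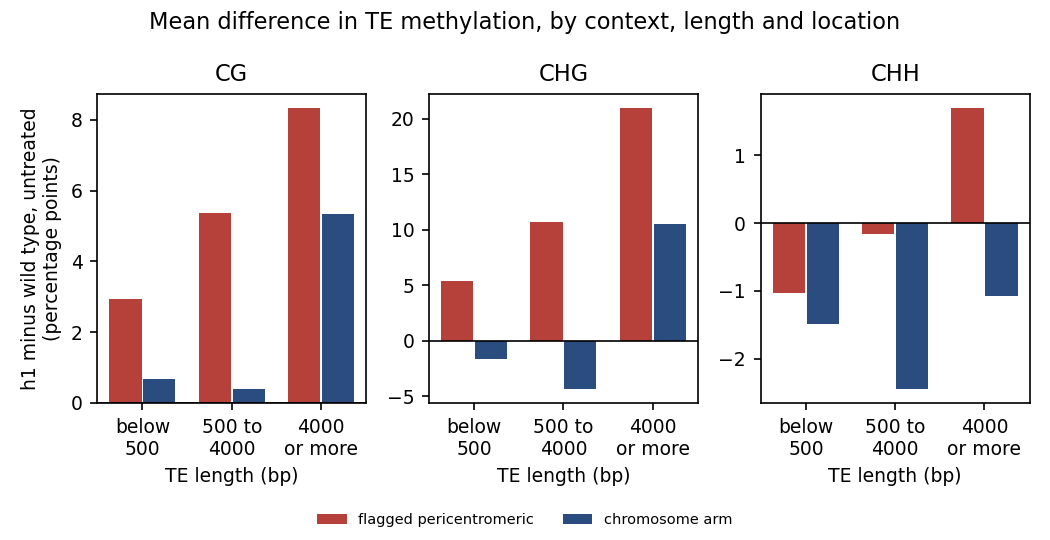
Mean difference in TE methylation between untreated h1 and wild type, by context, TE length and location. Each group is 1 pooled library pair, so no error across replicates is shown.

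Bins of 100 bp showed the same contrast between mutation and heat. In untreated plants, h1 had more methylation than wild type in 58704 CHG bins and less in 5474, against 8389 and 5604 in CG and 3689 and 9769 in CHH. After heat the numbers were 51788 and 5030 in CHG, 7774 and 5426 in CG and 5357 and 8227 in CHH. Heat in wild type gave 1 higher and 27 lower CG bins, 2 and 36 CHG bins and 259 and 715 CHH bins; in h1 it gave 1 and 45, 5 and 30, and 374 and 340.

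ONSEN stood apart in the methylation data as well. Median CG methylation of the 8 copies was 86.5% in untreated and 41.0% in heated wild type, and 95.4% and 30.0% in h1. CHG went from 27.3% to 13.8% and from 43.7% to 11.1%, and CHH from 13.7% to 8.45% and from 16% to 6.03%. The coverage of CG cytosines in the copies, scaled by library depth, was higher after heat by a median factor of 1.58 in wild type (0.946 to 3.77) and 2.41 in h1 (1.05 to 12). At CHG the factors were 1.35 and 2.40, and at CHH 1.27 and 2.28. AT5TE15240 went furthest, from 86.2% to 23.5% CG in wild type and from 94.5% to 8.47% in h1, with CG coverage ratios of 3.77 and 12. In AT3TE54550, with ratios of 0.946 and 1.05, CG went from 87.1% to 82.4% in wild type and from 96.0% to 84.6% in h1. Some copies are thinly covered, with 0.852 reads per CG in AT1TE12295 in untreated wild type.

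**Figure D4:**
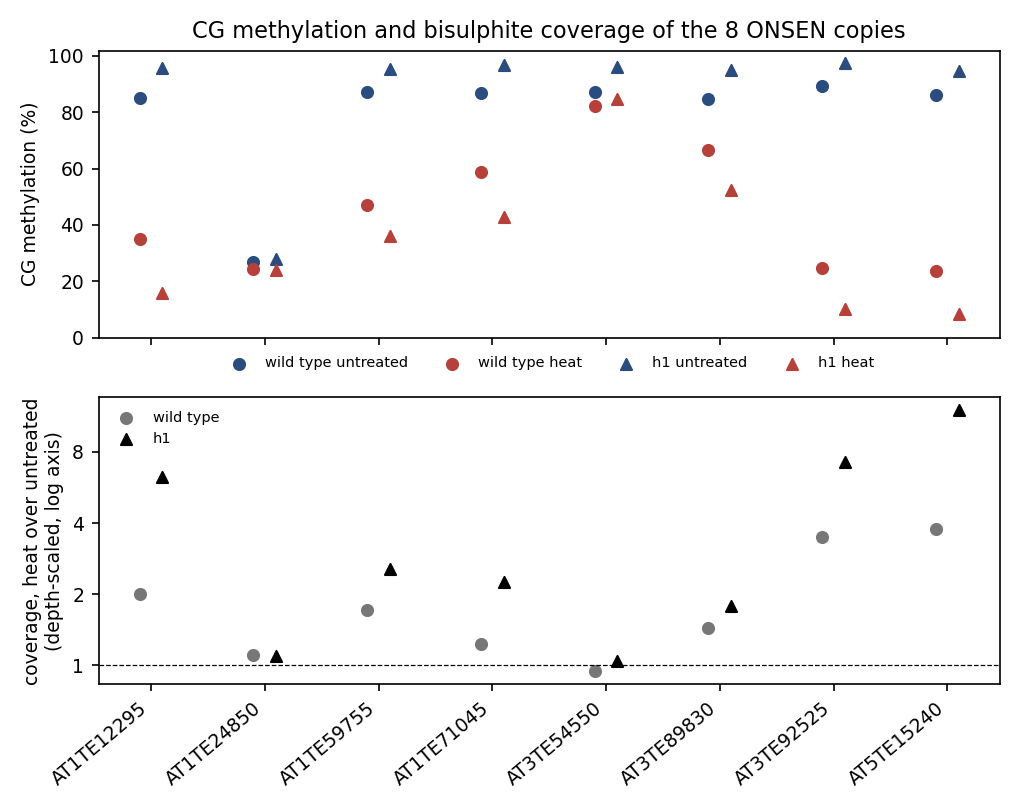
CG methylation of each ONSEN copy before and after heat (top) and its depth-scaled CG coverage ratio of heat over untreated (bottom, log axis). Each group is 1 pooled library pair.

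Methylation and transcripts were weakly related across TEs. In untreated h1 against wild type the Spearman correlation of the 2 differences was 0.0869 for CG, 0.135 for CHG and 0.0103 for CHH (adjusted p = 0.0063, 2.2e-05 and 0.69). Among TEs with a mean of at least 10 reads the first 2 were 0.0302 and 0.0291 and did not pass the test. After heat it was 0.171, 0.221 and 0.133 (adjusted p = 1.4e-09, 1.5e-15 and 6.2e-08). For heat in wild type it was -0.0875, -0.103 and -0.0392 (adjusted p = 0.00011, 6.7e-06 and 0.044), and for heat in h1 -0.0715, -0.227 and 0.0348 (adjusted p = 0.0032, 7.4e-22 and 0.090). The 14 TEs called higher in untreated h1 with CHG values differed in CHG by -12.6 points from matched TEs that were not called (permutation p = 0.0008, adjusted p = 0.0048 over 6 tests). Without matching their median difference was 0.965 points against 0.0514, and these calls come from only 2 untreated h1 libraries. After heat the 80 such TEs differed by 2.65 points from matched TEs (adjusted p = 0.0678; medians without matching 20.4 against 1.2), and none of the other tests passed.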

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

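The tests on copies sharing reads, on scaling, on cytosines of very high coverage and on regrouped libraries were chosen after the results were seen; the tests on ONSEN DNA were written before, but their CHG and CHH coverage was added after.

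The bisulphite data held a signal outside the methylation comparison, since CG coverage of the ONSEN copies, scaled by depth, was higher after heat by a median factor of 1.58 in wild type and 2.41 in h1 while their CG methylation was lower. A loss of methylation from the chromosomal copies does not match the methylated CG reads, whose median ratio of heat over untreated was 0.941 and 0.977. A general drop in long TEs does not match the other LTR elements of at least 4000 bp, which changed by -1.18 and -1.02 points. Unmethylated extra DNA of ONSEN after heat was to show as a factor above 1.5 in both genotypes. At CG the factors of 1.58 and 2.41 met this. At CHG and CHH, added after, h1 had 2.40 and 2.28, but wild type only 1.35 and 1.27. With 1 pooled library pair per group, extra DNA could account for the lower CG level and stays open.

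After heat ONSEN reads were higher in h1 and cmt2 than in wild type, and the response to heat differed between genotypes by a median of 2.71 (h1) and 3.27 (cmt2) on the log2 scale in a test of the difference itself. Of the value in h1, the lower untreated level, from 2 libraries, makes up more (-1.48) than the level after heat (1.1). At an adjusted p of 0.01 limma called 0 of the ONSEN copies in h1, both untreated and after heat. The limma calls after heat drop to 0 in h1 without h1 A, h1 B, h1 C or wild type replicate 2 or 3. In cmt2 they drop to 0 without cmt2 A or cmt2 B. Reads moving between near-identical copies do not account for the difference after heat, since the summed reads of the 8 copies differed by 1.09 and 2.82. That all other TEs fell relative to gene transcripts cannot be told apart from a rise of ONSEN, because no gene reads were used here and centring, with 1.11 and 2.89, shifts every TE alike. The effect of the missing proteins remains a hypothesis that this design names but does not test apart from scaling.

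The genome-wide CHH level was higher in h1 when weighted by reads. In untreated plants a few cytosines of very high coverage fit this, since the difference without them was -0.162 points. After heat it was 0.0201 points without them and 0.113 as a mean of site levels, and with 1 pooled library pair per group it stays open whether they account for all of it there. No biological explanation of that sign was tested.

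A test of the difference in heat response between h1 and wild type picked out 11 TEs with a higher and 2 with a lower response in h1. Besides ONSEN these were AT4TE42860 of ATCOPIA4 (2.74), AT5TE58950 of HELITRONY1B (2.53), AT5TE41395 of HELITRON5 (2.26), AT5TE46155 of VANDAL20 (-1.87) and AT5TE17365 of TAT1_ATH (-1.88). Of those named TEs, edgeR called only AT4TE42860, and limma only AT4TE42860 and AT5TE46155. The same test of the difference for cmt2 picked out 10 with a higher and 13 with a lower response, but edgeR gave 9 and 0 with none of the 13, limma 9 and 1, and centring 10 and 2 (43.5% to 83.3% higher). Besides ONSEN these were AT1TE10935 of ATCOPIA78 (3.97), AT5TE58950 (2.41), AT1TE28370 of VANDAL5 (-3.36), AT1TE75790 and AT1TE31080 of ATGP1 (-4.19 and -5.38), AT1TE36160 of ATCOPIA28 (-4.56) and 9 members of TAT1_ATH (median -2.88). CHH in pericentromeric TEs of at least 4000 bp differed after heat by -0.297 points in wild type and 0.295 in h1, and this difference was not tested.

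Regrouping the 6 libraries of a comparison gives 10 splits, too few for a verdict. The real grouping was the only 1 of 10 that gave as many calls for heat in wild type (1243), heat in cmt2 (1040), h1 after heat (141), untreated cmt2 (4), cmt2 after heat (50), heated h1 (1539) and heated cmt2 (1221) against untreated wild type, where the highest other split gave 0 each time. For the limma interaction of heat and cmt2, 5 of 100 drawn splits gave as many calls as the real 10, with 17 as the highest other value. The 4 besides the real one keep the grouping of the heated libraries and so its differences, which leaves that share without a verdict. The 94 splits that regroup heated libraries gave at most 1.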

How the results depend on the processing

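The use of other tools as alternatives, the restricted set of TEs, the pseudocounts, the highest coverage limit and the family left out were chosen after results were seen. Of 312 alternatives to the main values, 185 were labelled as the same, 122 moved, 2 lost their test and 3 reversed. For counts of calls that label allows a tolerance and does not mean an equal count. Against the main 1243 calls for heat in wild type, 1045 without heated wild type replicate 1 still counted as the same. Against the main 141 for h1 after heat, 96 without wild type replicate 1 counted as the same, and 84 without replicate 3 as moved. Of 2601 alternatives for named TEs, 2253 stayed the same, 343 lost their call in the same direction, 5 gained one and 0 reversed; all 462, 406 and 328 for heat in wild type, h1 and cmt2 stayed the same. Among lists 27 of 28 stayed the same, and associations of superfamilies numbered between 27 and 38 against 31. Where a library is left out of untreated h1, the lone library is assumed to vary like the other group. Among TEs with a mean of at least 10 reads and a deposited adjusted p, 2-fold changes were recovered in 9.70% of simulated cases for heat in cmt2. Depth and spread between replicates were not separated there. Unless said otherwise below, the cause of a change was not tested. Alternatives that need chloroplast cytosines or gene tables were not run.

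Counts of calls moved with thresholds, filters and tools. A mean of at least 10 gave 655 (heat in wild type), 815 (heat in h1), 588 (heat in cmt2), 120 (cmt2 after heat), 763 (heated h1) and 653 (heated cmt2 against untreated wild type). A log2 threshold of 2 gave 794 (heat in wild type), 22 (untreated h1), 44 (h1 after heat), 2 (untreated cmt2) and 980 (heated h1), and an adjusted p of 0.01 gave 9 (untreated h1), 44 (h1 after heat), 0 (untreated cmt2), 12 (cmt2 after heat) and 10 (heat response in cmt2). Deposited p-values adjusted over all TEs gave 723, 766 and 657 for heat in wild type, h1 and cmt2, 19 for untreated h1, and 903 and 734 for heated h1 and heated cmt2 against untreated wild type. limma on all TEs gave 0 (untreated h1), 247 (h1 after heat), 7 (untreated cmt2) and 231 (cmt2 after heat). The deposited calls gave 11 and 91 for cmt2 untreated and after heat, and pseudocounts gave 0 (0.5) and 7 (4) for untreated cmt2 and 97 (4) after heat. edgeR gave 685 (heat in wild type), 630 (heat in cmt2), 26 (cmt2 after heat), 815 (heated h1) and 706 (heated cmt2). For the heat response, limma gave 24 in h1, and in cmt2 edgeR 9, limma 10 and centring 12. Leaving out 1 library gave at most 36 calls for untreated h1, where fits with a lone h1 library cannot be judged. It gave from 69 to 215 for h1 after heat, 0 for untreated cmt2 and from 2 to 216 for cmt2 after heat.

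With the replicate number as a block, heat in wild type gave 1302 calls against 1243. Its same-number correlations were 0.0883, 0.247 and 0.0461, not all over 0.1, so these libraries were not treated as paired; replicate 3 correlated best with number 1 (0.270). In untreated cmt2 the block gave 5 against 4. It was run for these 2 comparisons alone and kept the call of every named TE in them. For the other comparisons no paired analysis was run. The column numbers of h1 and of heated cmt2 do not match the replicate numbers of the labels in full, and the bisulphite libraries are pooled.

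Methylation differences between genotypes and with heat are given for coverage of at least 10, the mean of site levels, and without cytosines above 500 reads. CG in h1 minus wild type was 1.55, 1.41 and 1.37 untreated and 0.702, 1.49 and 0.828 after heat; heat gave -1.44, -0.579 and -1.48 in wild type and -2.28, -0.494 and -2.02 in h1. CHG gave 2.18, 2.70 and 2.02, then 1.73, 2.75 and 1.64, then -0.650, -0.353 and -0.595, then -1.09, -0.305 and -0.976 in that order. CHH gave 0.310, -0.154 and -0.162, then 0.502, 0.113 and 0.0201, then -0.256, -0.220 and -0.251, then -0.0632, 0.0466 and -0.0688. Weighted by reads, pericentromeric TEs of at least 4000 bp gave 7.88 (CG), 20.8 (CHG) and 1.65 (CHH) for h1 and -1.37, -0.896 and -0.319 for heat in wild type, and arm TEs of 500 to 4000 bp gave 1.43, -1.71 and -2.15 and -1.33, -0.935 and -0.493. Signs turned for CG of short arm TEs in heated h1 (-0.275), CHH of pericentromeric TEs of 500 to 4000 bp in untreated h1 (0.274), and CHH with heat in h1 of short pericentromeric (-0.0436) and middle-sized arm TEs (-0.0155). A lower threshold gave 40535 and 40635 CG bins and 45964 and 40178 CHH bins for h1 untreated and after heat. For heat in wild type and h1 it gave 208 and 267 CG, 75 and 96 CHG, and 2129 and 2446 CHH bins. Bins of 200 bp gave 6182 and 5828 CG and 5268 and 5117 CHH bins for h1, 299 and 188 CHH bins for heat and 18 CHG bins for heat in h1, where coverage of 10 left 29 CG bins. At a mean of at least 10, the correlations of methylation and transcripts in untreated h1 were 0.0302 (CG) and 0.0291 (CHG) and lost their test.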

Other observations

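The tests of windows along chromosomes, with all libraries and with 1 left out, and the scan of coverage were chosen after the values were seen.

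TEs lower in h1 than in wild type after heat gathered on chromosome 2 when all libraries were used. Between 6000001 and 7000000, 13 of the 49 TEs called lower lay among 49 tested there (Fisher's exact test, odds ratio 17, adjusted p = 2.3e-08 over 242 windows), and 8 more lay between 7000001 and 8000000 (odds ratio 14.2, adjusted p = 0.00012). AT2TE28350 of HELITRON3 and AT2TE29180 of ATREP3 are among them. In heated cmt2, 5 of the 26 TEs called lower lay in the second window (odds ratio 15.6, adjusted p = 0.0048), against the same wild type libraries. The lower calls vary from 17 to 114 in h1 and from 0 to 183 in cmt2 when 1 library is left out. The first window passed in 3 of 6 such fits in h1, failing without h1 A, h1 C or wild type replicate 3 (odds ratios 6.20, 10.4 and 8.18, adjusted p = 0.407, 0.162 and 0.515). The second passed in 2 of 6 in h1 and 2 of 6 in cmt2. Neighbouring TEs can lie in 1 transcript and are not independent.

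A scan of 7532 TEs for bisulphite coverage found 51 with a depth-scaled ratio of heat over untreated of at least 1.5 in wild type and 21 in h1. Of 5 TEs with such a ratio in both genotypes, 4 belong to ATCOPIA78. The median over all TEs was 0.988 in wild type and 0.937 in h1.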
